A study of Mus musculus and Rattus norvegicus with 4 samples.

How the data were processed

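MEF2A was immunoprecipitated from sonicated nuclei, and libraries were made by ChIP-exo with a size selection on a gel, per the labels' protocols. C2C12 cells had been kept for 48 h in medium with 2% horse serum. The rat sample carries the C2C12 treatment text in its labels, so no treatment is stated here for the cardiomyocytes. Samples were grouped by the antibody and organism given in their titles, with 1 library per group. The IgG libraries were not analysed here, and whether the peak caller used them as control is not given in the sources used here.

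The submitters' processing notes name CASAVA 1.7.0, BWA 0.5.9, Picard, SAMtools and MACS 1.4.2, and the genome builds mm10 and rn5, with no settings. The authors deposited a peak list for each MEF2A library, not a pooled one, with chromosome, start, end, name and a score for each peak and no header. MACS of this generation writes a score of -10 times the log10 of the peak's p-value, and the lowest deposited score is just above 50 in both lists. No header states this scale, so the deposited score is used to describe, rank and filter peaks within a list. Drawing mouse peaks to the rat scores assumes that both lists share a scale, which was not tested. No summits, fold enrichments, read counts or depth were given, so no counting interval was computed for a peak. A file that lists only peaks past a threshold says nothing of weaker sites. Peak starts were read as counting from 0 and are printed counting from 1. Mouse peaks were taken as mm10 and rat peaks as rn5, the only build of each species named, and mouse positions on chromosome Y exceed the length of that chromosome in the build before mm10.

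Genes came from the RefSeq gene table of GRCm38.p6, the assembly behind mm10, with 21887 protein-coding genes on placed chromosomes. It gives a start and end for each gene but no strand, exon or start site, and no genome sequence or rat annotation was used. The plan made before the data were examined called for distances to start sites, and gene spans replaced these. The planned motif search, the location of rat peaks relative to genes and the comparison of bound genes between the species were not run for the same reason. Each mouse peak was assigned to the nearest protein-coding span within 100 kb, with distance 0 inside a span. The 26 peaks inside several spans counted for each gene.

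Location was tested against 1000 random placements of the peaks, with the same widths and chromosomes, between the first and last annotated gene of each chromosome. For gene lists, each gene's territory was the length of genome that would be assigned to it. Each of 18 lists was compared with 10000 random lists with the same number of genes from each of 10 classes of territory length, one-sided, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. All 652 listed symbols were found, 7 of them through a synonym, giving 644 distinct genes. Peaks and genes are not replicates, so these p-values describe the deposited lists. For the correlation of score with width, both lists were resampled 1000 times, a step chosen after the values were seen. Fisher's exact test was used for shares of peaks, and exact binomial 95% intervals cover counting error only.

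The genes named are those of the 10 highest-scoring peaks, up to 4 members of each list by their highest-scoring peak, all members of the list of MAPK genes and dual-specificity phosphatases with a peak, Dusp6 and the MEF2 genes. Further list members are named without values. The results of 1 list, and some genes that this rule takes, are not reported here. Myod1, Myog and Myf5, and the genes first named in the closing section, were chosen after the values were seen, as were the comparison of close pairs with random placement and the correlation of score with width. The list test was checked on simulated data. With 2797 randomly placed peaks and 21887 genes, 1 of 360 list tests in 20 rounds passed, and a sarcomere list with 20 planted genes passed in 100% of 20 rounds. The planted excess was large against the matched mean of 4.23 genes, so the check does not measure power for smaller excesses. Its peaks were placed without regard to genes, so it does not cover peaks that favour active genes. Alternatives were a score of at least 100 or 200, merging peaks under 1 kb apart, other distance limits, Fisher's exact test without matching and, added after seeing the data, assignment to the nearest end of a span and leaving out dense runs and peaks over 2 kb wide. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.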

Results

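MEF2A occupancy was mapped by ChIP-exo in C2C12 cells, a mouse skeletal myoblast line, after 48 h in differentiation medium, and in primary cardiomyocytes from newborn rats. ChIP-exo is chromatin immunoprecipitation followed by exonuclease trimming of the bound DNA, which narrows the sequenced ends to the edges of the protein footprint. MEF2A is a transcription factor of the myocyte enhancer factor 2 family, which regulates muscle genes. The series held 4 libraries, a MEF2A and a normal rabbit IgG library for each cell type, with 1 library per group. The 2 MEF2A peak lists were analysed, and read depth is unknown because each list gives only a position and a score per peak. With no replicates, every statement describes these libraries, and the tests compare peaks or genes within a list with random expectation.

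The first comparison set the MEF2A peak lists of the skeletal and the cardiac cells side by side. C2C12 cells gave 2797 peaks and rat cardiomyocytes gave 1868. Peaks in C2C12 cells were wider, with a median of 144 bp (quartiles 116 and 230 bp) against 113 bp (quartiles 99 and 140 bp). The authors' score, higher for stronger peaks, started just above 50 in both lists. Its median was 77.0 in C2C12 cells and 62.0 in cardiomyocytes. Scores of 200 or more were held by 424 C2C12 peaks (15.2%) and 71 cardiomyocyte peaks (3.80%). Scores depend on the depth and background of each library, so these values describe each list and cannot be assigned to the cell type.

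**Figure D1:**
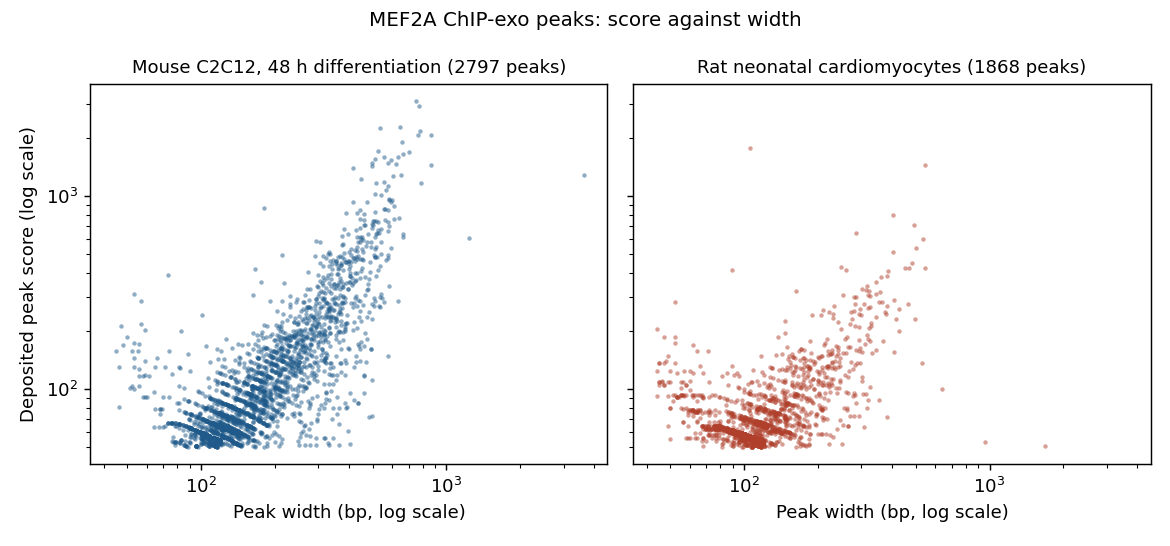
Deposited score (log scale) against peak width in bp (log scale) for the MEF2A peaks of mouse C2C12 cells (left) and rat cardiomyocytes (right), with each point a peak. The mouse list reaches a score of 3100 and the rat list 1764, and the Spearman correlation across peaks is 0.73 in the mouse list and 0.30 in the rat list.

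The strongest C2C12 peak (score 3100) lay on chromosome 4 at 95636922 to 95637673 (mm10), inside the span of Fggy, which encodes a carbohydrate kinase. The second (score 2912) lay on chromosome 19 at 4992552 to 4993322, inside the span of Npas4, an activity-regulated transcription factor gene. Matn2, a matrilin of the extracellular matrix, held the third (score 2277), and Tprg the fourth (score 2253). The fifth (score 2172) was 3.03 kb from Dot1l, the histone H3 lysine methyltransferase gene. Pakap (score 2067), Mtus1 (score 1891) and Akap6, which encodes a kinase anchoring protein of the muscle nuclear envelope (score 1711), also contained peaks of the first 10. The remaining 2 were farther from any protein-coding span, at 42.2 kb from Tex44 (score 2067) and 78.9 kb from Crygf (score 1677).

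In rat cardiomyocytes the highest score (1764) belonged to a peak of 106 bp on chromosome 2 at 134264789 to 134264894 (rn5). The next was a peak of 546 bp on chromosome 1 at 227199924 to 227200469 with a score of 1448. The third to the fifth lay on chromosome 15 at 65033939 to 65034342 (score 796), chromosome 1 at 117364889 to 117365382 (score 706) and chromosome 7 at 11995597 to 11995882 (score 642). The other 5 of the first 10 scored from 426 to 595 and lay on chromosomes 5 (with 2 peaks), 13, 7 and 6. No rat annotation was used, so these peaks carry no gene names, and the genes bound in both cell types were not compared here. Chromosome 1 held the most peaks in the rat list (223) and chromosome 12 the fewest (31).

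Peaks in both lists came in close pairs more often than under random placement, though most peaks stood alone. Neighbouring peaks less than 1 kb apart numbered 237 in C2C12 cells and 91 in cardiomyocytes. Random placement of the same peaks between the first and last peak of each chromosome gave a mean of 3.93 and at most 10 such pairs in the mouse, and a mean of 1.49 and at most 7 in the rat (1000 placements each). The median gap within these pairs was 52 bp in C2C12 cells and 35 bp in cardiomyocytes. Merging them left 2560 mouse and 1777 rat regions, of which 199 and 83 held several peaks. Random placement treats peaks as independent, so it cannot tell separate sites from a single region that the peak caller split.

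The next question was where MEF2A bound relative to genes in C2C12 cells. Of the 2797 peaks, 1316 (47.1%) lay inside the span of a protein-coding gene, against a mean of 40.1% under random placement (central 95%, 38.4 to 41.9%). Within 1 kb of either end of a protein-coding span lay 190 peaks (6.79%), which was 2.06 times the random mean of 3.30% (central 95%, 2.65 to 4.01%). Both shares exceeded all 1000 placements (one-sided permutation p = 0.001, the smallest these placements can give). Peaks near a gene end were not concentrated among the strong ones. The share was 6.72% (exact 95% interval 4.98 to 8.84%) in the highest quartile of score and 7.86% (5.97 to 10.1%) in the lowest (two-sided Fisher exact p = 0.47 over peaks). The gene table gives neither strand nor exons, so start sites, promoters, exons and introns were not distinguished, and placement ignored which sequence can be aligned.

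With each peak assigned to the nearest protein-coding span within 100 kb, 2306 C2C12 peaks (82.4%) were assigned to 1691 genes, or 7.73% of the 21887 protein-coding genes. Of these genes 428 held 2 or more peaks. Assignment by proximity does not show that a gene is regulated. The lists of genes below were fixed beforehand and compared with 10000 random lists of the same size, matched on the length of genome assigned to each gene.

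Structural muscle genes had peaks more often than matched random lists, though not alone, since fibroblast and matrix genes (described below) did as well. Of 66 sarcomere and contractile genes, 24 (36.4%) had a peak, 5.67 times the mean of matched random lists (4.23 genes, central 95% 1 to 8). The strongest was Ankrd1, a titin-associated stress-response gene (chromosome 19, 36111965 to 36119844), with 4 peaks and a top score of 1275 at the end of its span. Des, encoding the intermediate filament desmin (chromosome 1, 75360292 to 75368579), had a peak of score 925 at 12.5 kb. Myl4, an embryonic and atrial myosin light chain, held a peak of score 738, and Lmod2, an actin filament nucleator of the thin filament, a peak of score 665. The other members with a peak were Acta1, Myh2, Myh3, Mylpf, Tnni1, Tnni2, Tnnt3, Tpm2, Ttn, Myom2, Myom3, Myoz2, Csrp3, Lmod3, Xirp1, Flnc, Pdlim3, Synpo2l, Smyd1 and Mypn. Costamere and adhesion genes, which couple the sarcomere to the membrane, gave 22 of 46 (47.8%), 3.39 times the matched mean of 6.48. They included Sspn (4 peaks, top score 804), encoding sarcospan, Sgce (709), a sarcoglycan, Utrn (584), the dystrophin homologue utrophin, and Sntb1 (574), a syntrophin. Among peaks scoring 100 or more the costamere ratio was 5.52. For both of these lists the one-sided permutation p was 0.0001, the smallest the draws can give, and the Benjamini-Hochberg adjusted p over 18 lists was 0.00045.

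**Figure D2:**
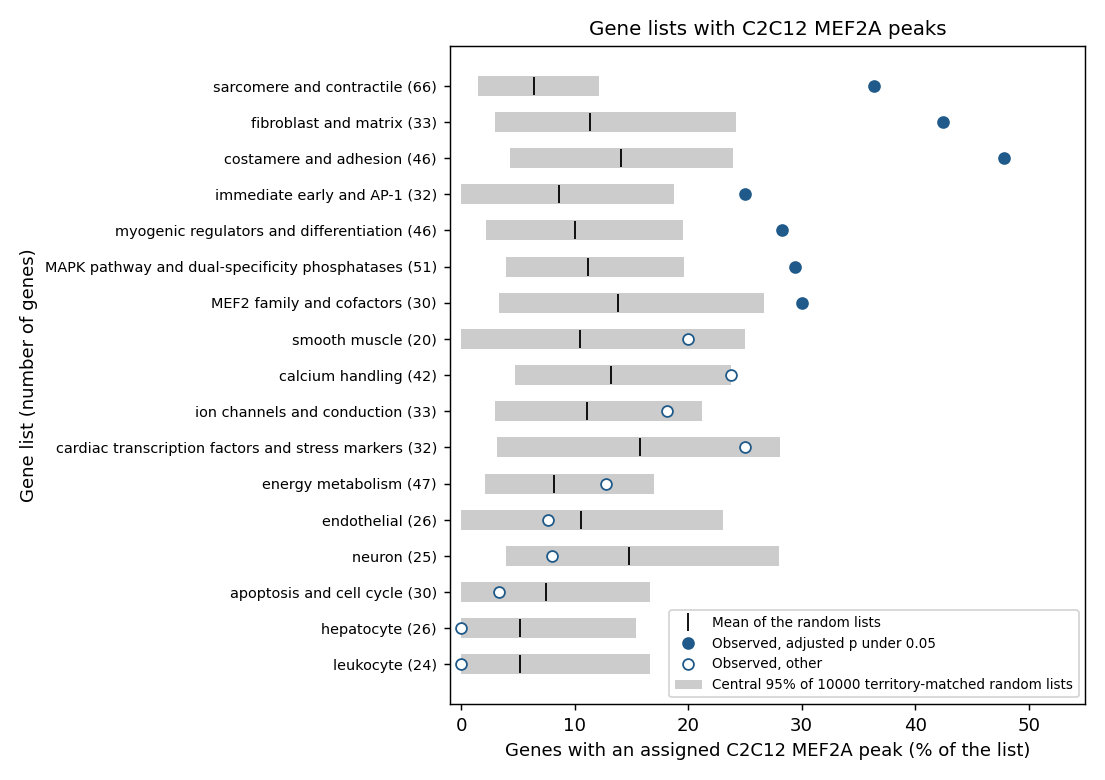
Percentage of genes with an assigned C2C12 MEF2A peak (x axis) in each gene list described (y axis, number of genes in brackets), as points, filled where the adjusted p is under 0.05. Grey bars are the central 95% and black ticks the mean of 10000 matched random lists; the sarcomere list lies at 36.4% and the hepatocyte and leukocyte lists lie at 0.

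Genes of muscle differentiation were also over-represented. In the list of myogenic regulators and differentiation genes 13 of 46 (28.3%) had a peak, 2.82 times the matched mean of 4.61 (permutation test, adjusted p = 0.00072). Eya1, a transcriptional coactivator of muscle progenitors, had its strongest peak (score 1225) 49.0 kb away. Cavin4, a muscle caveolar protein, held a peak of score 359, Celf2, a splicing regulator, one of 342, and Fbxo32, the ubiquitin ligase atrogin-1, lay 6.86 kb from one of 124. Myod1, Myog and Myf5 had no assigned peak. The MEF2 family and cofactor list gave 9 of 30 (30.0%), 2.18 times the matched mean of 4.13 (permutation test, adjusted p = 0.0304). Its strongest members were Mrtfa (211), a coactivator of serum response factor, Hdac5 (195), a repressor of MEF2, Cabin1 (172) and Tead1 (120.4, with 5 peaks). Of the MEF2 genes themselves only Mef2c (chromosome 13, 83504017 to 83667079) was assigned peaks. It had 3, with scores of 66.2 at 42.0 kb and of 51.0 and 100.2 inside the span. The peak nearest to Mef2a was 327.9 kb away, that nearest to Mef2d 320.9 kb and that nearest to Mef2b 514.8 kb. Neither list passed the threshold among peaks scoring 100 or more, where the adjusted p was 0.144 for the myogenic list and 0.109 for the MEF2 list.

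The title of the series names Dusp6, which encodes a phosphatase that inactivates ERK. In the list of MAPK genes and dual-specificity phosphatases 15 of 51 (29.4%) had a peak, 2.64 times the matched mean of 5.69 (permutation test, adjusted p = 0.0012). Dusp6 (chromosome 10, 99263231 to 99267489) was assigned 4 peaks. The peak at 99263029 to 99263134 lay 97 bp from the lower-coordinate end of the span and scored 68.2. A pair at 99250796 to 99250893 and 99250938 to 99251065 lay 12.3 and 12.2 kb away on the same side and scored 60.0 and 93.5. The fourth, at 99297814 to 99297926, lay 30.3 kb beyond the other end and scored 58.9. The strongest Dusp6 peak ranked 1111 of 2797. Other phosphatases with a peak were Dusp1 (119.5, at 22.4 kb), Dusp10 (115), Dusp8 (93.4), Dusp5 (73.3, at 1.86 kb) and Dusp26 (56.6, at 10.4 kb). Among kinases, Mapkapk2, a target of p38, had the strongest peak (307), followed by Map3k4 (210) and Map2k6, an activator of p38 (99.9, at 83.2 kb). The p38 genes Mapk14 (79.3) and Mapk12 (54.95) contained weaker peaks, as did Araf (62.3). The signalling inhibitor genes Spred2 (132, at 89.0 kb) and Spry2 (54.1, at 1.44 kb) also had a peak. With peaks scoring 100 or more, 5 of the 51 genes had a peak and the list no longer passed (permutation test, adjusted p = 0.204); no Dusp6 peak reached that score.

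**Figure D3:**
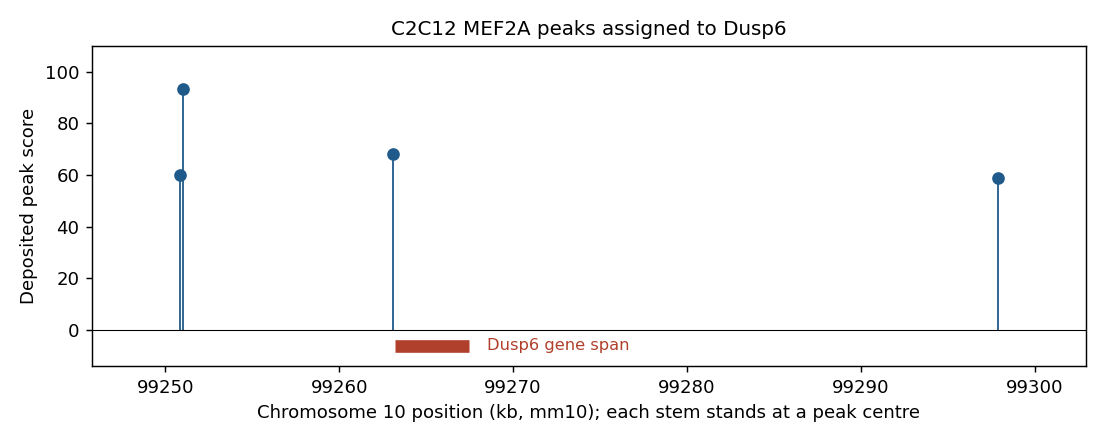
Positions on mouse chromosome 10 (x axis, kb, mm10) and deposited scores (y axis) of the 4 C2C12 MEF2A peaks assigned to Dusp6, whose span is drawn in red. Scores run from 58.9 to 93.5, and a peak lies 97 bp from the left end of the gene.

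Immediate early and AP-1 genes gave 8 of 32 (25%), 2.91 times the matched mean of 2.75 (permutation test, adjusted p = 0.00771). Btg2, an antiproliferative gene, had a peak of score 615 at 3.65 kb, Jun a peak of score 577 at the end of its span, Atf3 a peak of 286 and Nr4a1 a peak of 131. Fos, Fosb, Fosl2 and Klf6 were the other members. With assignment limited to 10 kb, 6 members had a peak, 6.72 times the matched mean. This list did not pass among peaks scoring 100 or more (permutation test, adjusted p = 0.109).

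Lists named for other cell types were included for contrast. Without expression data, it is unknown which of their genes are active in C2C12 cells. Fibroblast and matrix genes gave 14 of 33 (42.4%), 3.72 times the matched mean of 3.76 (permutation test, adjusted p = 0.00045). Postn, encoding periostin, had a peak of score 763 at 89.2 kb, and Thy1 a peak of 171 at 98.0 kb. Col4a2 contained a peak of 199.5, and Ccn1, a matricellular growth regulator, had 4 peaks with a top score of 198 at 1.75 kb. Fn1, Lox, Loxl1, Ccn2, Tgfb2, Timp3, Col1a1, Col1a2, Col3a1 and Col5a2 also had peaks. Endothelial genes (2 of 26, adjusted p = 1) and neuronal genes (2 of 25, adjusted p = 1) did not pass the permutation test. The endothelial members were Vwf (93.9) and Ets2 (52.1, at 21.1 kb), and the neuronal members Syn2 (409.8, at 1.54 kb) and Nefl (54.7, at 11.9 kb). No hepatocyte gene of 26 and no leukocyte gene of 24 had a peak, against matched means of 1.36 and 1.26. The central 95% of matched random lists was 0 to 4 genes for both, so a count of 0 lies within random expectation. The permutation test was one-sided for an excess, so it cannot show that these lists had fewer peaks than matched lists. Smooth muscle genes gave 4 of 20, 1.91 times the matched mean (permutation test, adjusted p = 0.221), with Synpo2 (517), Itga8 (197, at 57.1 kb), Npnt (116, at 12.7 kb) and Cald1 (54.95, at 0.31 kb).

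The lists of calcium handling, cardiac, ion channel, energy metabolism, and apoptosis and cell cycle genes did not pass the main test. Calcium handling genes gave 10 of 42 (1.80 times the matched mean, permutation test, adjusted p = 0.0686), led by Trdn (236, at 9.94 kb), encoding triadin of the junctional reticulum, Orai1 (187, at 5.62 kb), Rcan2 (164) and Camk2d (144). This list passed in 2 of 6 alternatives, among them assignment to the nearest gene end (2.26 times, permutation test, adjusted p = 0.0135). Cardiac transcription factors and stress markers gave 8 of 32 (1.58 times, permutation test, adjusted p = 0.209), with Tbx20 (356), Mitf (249), Foxp1 (189) and Meis1 (109.97) highest. Ion channel genes gave 6 of 33 (1.63 times, permutation test, adjusted p = 0.221), with Kcna5 (138, at 34.4 kb) and Kcnj8 (87.6, at 16.1 kb) among them. Energy metabolism genes gave 6 of 47 (1.56 times, permutation test, adjusted p = 0.24), including Prkag3 (848), a muscle subunit of AMP-activated kinase, Ppargc1a (277, with 4 peaks), Lpl (70.2, at 4.80 kb) and Gbe1 (66.2). In the apoptosis and cell cycle list only Cdkn2a of 30 genes had a peak (221, at 23.7 kb, permutation test, adjusted p = 1). A list that missed the threshold is not shown to differ from the lists that passed, since lists were not tested against each other.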

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

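The assignment to the nearest gene end and the setting without dense runs and wide peaks were chosen after seeing the data, as was merging for location and lists. Peaks scoring 100 or more numbered 1029 in C2C12 cells and 306 in cardiomyocytes, and peaks scoring 200 or more 424 and 71. At 100 or more, 759 genes were assigned and 4 lists passed in place of 8, among them sarcomere, costamere and matrix. The myogenic, MEF2, MAPK and immediate early lists then stood at 2.32, 2.57, 1.93 and 3.22 times their matched means, with fewer peaks entering by construction. Each of these 4 lists passed in 5 of 6 alternatives and failed only at a score of 100 or more. Their adjusted p (permutation or Fisher's exact test) ran from 9.07e-05 to 0.144 (myogenic), 0.000794 to 0.109 (MEF2), 1.57e-05 to 0.204 (MAPK) and 0.0012 to 0.109 (immediate early). Each of the other 4 lists passed in 6 of 6. Merging gave the same counts of genes with a peak as the main test, and Fisher's exact test used the same assigned genes. Those alternatives therefore do not check which genes have a peak, and only the score of 100 or more selects peaks by score. Calcium handling passed with Fisher's exact test (3.08 times) and with the nearest gene end (2.26 times), and the cardiac list with Fisher's exact test (3.24 times). Without matching on territory, Fisher's exact test gave 6.19 times for costamere and 3.88 times for MEF2. Smooth muscle stood at 3.09 times at a score of 100 or more, without passing. Lists that were not called changed direction in 2 cases, apoptosis and cell cycle at a score of 100 or more (1.02 times, 1 gene) and neuron with Fisher's exact test (1.04 times). The share of peaks within 1 kb of a gene end stayed above the random mean with a score of 100 or more (6.22% against 3.4%) and with all annotated genes (12.4% against 6.75%). It did so too with merged peaks (6.99% against 3.34%) and without dense runs and wide peaks (6.70% against 3.29%). In a 5 kb window the excess was smaller, 16.8% against 12.7%, or 1.33 times in place of 2.06. Leaving out those runs and wide peaks gave 1681 genes and 8 lists. Depth is unknown, and no replicate shows which weak peaks recur. Other settings chosen in advance, for motifs, for rat locations, genes and lists, and for genes bound in both species were not run, because no genome or rat annotation was used. No paired analysis was possible because each group has 1 library.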

Other observations

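Tests of dense runs, of very narrow peaks, of the resampled correlations and of territories for calcium handling genes were chosen after the result was seen, as was the correlation of score with width itself. The noncoding genes and pseudogenes, Fgf7, Fam227b, Has2 and the genes at dense runs were chosen after their values had been seen. In C2C12 cells 6 peaks lay inside Malat1 (chromosome 19, 5795690 to 5802672, top score 161) and 4 inside Neat1 (top score 139), both abundant nuclear long noncoding RNAs. A run of 12 peaks over 21.5 kb on chromosome 11 covered Mir21a, whose nearest peak was 50 bp away, and the end of Vmp1, which was assigned 13 peaks. Mir100hg held 3 peaks with a top score of 548, and the peak of score 577 at Jun also overlapped the lncRNA gene Junos. Among other microRNA genes looked up, the nearest peak lay 3.8 kb from Mir22 (score 50.4), 43.9 kb from Mir206, 47.7 kb from Mir133b (score 139), 340.5 kb from Mir486, 397.6 kb from Mir499, 640.1 kb from Mir1a-2 and 721.6 kb from Mir208a. Fgf7, a growth factor gene inside the span of Fam227b, was assigned 6 peaks with a top score of 404. That top peak was also assigned to Fam227b. Has2, a hyaluronan synthase gene, was assigned 5 peaks with a top score of 109.

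The C2C12 list held 13 runs of 4 or more peaks with gaps under 10 kb, in all 78 peaks. Chance placement of peaks independently of each other is argued against, since 0 of 1000 random placements gave as many runs and the most in any was 1. The list also held more close pairs than these placements gave, and merged peaks were not placed. The test therefore cannot tell a run from a single region split into several peaks. Some runs were short, such as that of 4 peaks over 1 kb on chromosome 4. The runs include Malat1, Neat1, Mir21a with Vmp1, Ccn1, Ankrd1, Map3k7cl and sequence with no annotated gene on chromosomes 4, 13, 16 and Y. A candidate explanation is spread signal without a strong site, as might come from highly transcribed chromatin or repeated sequence. Of the 13 runs, 4 had a peak above the 90th percentile of score (278), and the median score in runs was 72.4 against 77.5 elsewhere. These values cannot decide it. The number of such runs when scores are unrelated to position was not computed, and the medians were not tested. The runs at Ankrd1 (top score 1275) and Ccn4 (645) are among those 4, and no biological explanation was tested.

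Sarcomere, costamere and myogenic genes had peaks more often than matched genes, and for calcium handling genes the result depended on how peaks were assigned. The size of gene territories is argued against as the whole cause for the sarcomere list, which stood at 5.67 times lists matched on territory and 4.71 times with Fisher's exact test, which does not match. Matching lowered the ratio from 6.19 to 3.39 for costamere genes and from 3.66 to 2.82 for myogenic genes. For calcium handling genes it fell from 3.08 to 1.80. Territory may therefore account for part of the excess in these lists. For calcium handling (permutation test, adjusted p = 0.0686 after matching) it stays open as the whole cause. With peaks assigned to the nearest gene end, that list did pass against matched lists (2.26 times, permutation test, adjusted p = 0.0135). Fibroblast and matrix genes exceeded matched lists as well, so a further explanation was weak peaks at any active gene: among assigned peaks, 5% of those scoring 200 or more (18 of 360) and 4.93% of the rest (96 of 1946) lay at genes of the sarcomere, costamere, calcium and myogenic lists (odds ratio 1.01, 95% interval 0.57 to 1.72, Fisher exact p = 0.90). This leaves that explanation open, because the interval allows a higher or a lower share among strong peaks, and no expression data were used to match lists on activity.

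Across peaks, which are not independent replicates, score followed width less closely in the rat list (Spearman's rho 0.30) than in the mouse list (0.73). A narrower range of scores in the rat list is argued against as the whole cause: mouse peaks drawn to the rat scores gave a median rho of 0.49 (central 95% of 1000 draws, 0.45 to 0.52), and the difference from the rat rho was 0.189 (95% bootstrap interval over peaks of both lists, 0.121 to 0.262). Peaks under 75 bp made up 8.24% of the rat list (154 peaks, exact 95% interval 7.04 to 9.58%) and 1.75% of the mouse list (49 peaks, 1.30 to 2.31%), a difference beyond counting error (Fisher exact p = 3.5e-26). Without them the rat rho of 0.452 still lay under the central 95% of mouse draws treated in the same way (0.470 to 0.535, median 0.503), which leaves out the error of the rat list, while the bootstrap interval of the difference of 0.0508 just included 0 (-0.0041 to 0.117), so the tests differ and very narrow peaks together with the range of scores are neither excluded nor shown as the whole cause. The narrow peaks scored higher than other peaks in both lists (median 117 against 75.9 in the mouse and 78.1 against 60.8 in the rat), and whether they are piles of reads at repeated sequence stays open, as does a difference between the species or cell types.

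The widest C2C12 peak, 3636 bp on chromosome 1 at 24611531 to 24615166 with a score of 1283, overlapped the pseudogenes Gm10222 and Gm10925. Chromosome Y held 8 C2C12 peaks, of which 4 formed a run at 90739241 to 90741179. Whether reads of similar sequence elsewhere were placed at the widest peak or on chromosome Y was not tested. MEF2A binding at these places is therefore not established. The rat list held 3 runs of 4 or more peaks, the longest of 8 peaks over 20.1 kb on chromosome 7 at 5299637 to 5319751.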
